A study of Arabidopsis thaliana with 28 samples.

How the data were processed

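The series compared wild-type Arabidopsis thaliana (Columbia-0) on medium with 2% sucrose and on medium without it, with 14 arrays of total RNA per group. Groups and replicate numbers came from the sample labels. The deposited table held 1 intensity per probe and array on a linear scale, never below 0, for 3439 probes with spot numbers up to 4607. The highest value was 100 after rounding on 20 arrays and at least 81.5 on the others, as if each array had been scaled to a maximum. The scanner, the background correction and the normalization used by the authors are not given in the sources used here, so the absolute scale and the background level stay unknown. All columns matched a sample.

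Values were raised to a floor of 0.0483, the 5th percentile of all positive values, and log2 transformed. Between 409 and 601 probes per array were listed at 0, and a fold against values at the floor depends on the floor chosen. Log2 medians of the arrays spanned 1.44, so arrays were quantile normalized, by a rule set before the data were examined. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided moderated test) in R 4.3.3, with Benjamini-Hochberg adjustment over all 3439 probes and a threshold of 0.05. Positions below are projections on the axis from the mean of the other no-sucrose sets (0) to that of the other sucrose sets (1).

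The fit planned before the data were examined took the 28 arrays as separate samples. Arrays with consecutive numbers in a group correlated at 0.903 to 0.989 after normalization, against at most 0.973 between sets, and 26 of the 28 were closest to their consecutive partner. The SD was 0.328 between the arrays of a set and 0.572 between sets of a group (log2). Consecutive arrays were therefore averaged and counted as 1 sample, which departs from the plan. The change was proposed from correlations of the deposited values and made final after the counts of both fits had been seen. The labels do not say that these arrays are duplicates, and they name no separate cultures, so p-values measure only the spread between these sets, which may be technical. No label gives a hybridization batch, an array lot or a scan.

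Gene names came from the platform annotation, updated by gene identifier through the RefSeq table of assembly TAIR10.1. Of the 3439 probes, 692 had 1 gene, 870 had several and 1877 were not listed there and are unnamed here. Of the 692, 690 matched the RefSeq table, with 689 distinct genes. No gene was named from a probe with several genes, and no positions are printed because no genome build is named for the table. AT2G25870 had 2 probes that disagreed, with log2 fold changes of 0.57 and -0.36.

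The named genes were, per direction, the 10 largest log2 fold changes among probes of 1 gene past the threshold with the mean of the higher group above the median of all probes; per gene list the 4 members with the smallest adjusted p that passed, or up to 2 where none passed; and 12 sugar-responsive index genes. All 7 measured list genes are given, which adds members that did not pass. The lists held 288 genes and were fixed before the data were examined. They covered light harvesting and photosystems, the Calvin cycle and photorespiration, starch and sucrose metabolism, glycolysis, phenylpropanoids and anthocyanins, dark and sugar starvation, nitrogen assimilation, sugar transporters, dehydration and cold, heat shock, pathogen and jasmonate genes, cell wall and growth, markers of root, seed and flower, and cytosolic ribosomal proteins. The ribosomal proteins were searched by name in gene symbols and synonyms only, which found 2 genes and leaves most of that family out. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry; this left 1 list.

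The procedure was tested on simulated data with the means and spreads of the 3439 probes and 7 sets per group. It called 17.9% of probes changed by 0.5 on the log2 scale, 55.2% of those changed by 1 and 90.9% of those changed by 2. Of its calls, 7.63% were of unchanged probes. The simulation changed 67, 67 and 66 probes by these sizes, far fewer than were called in the data. It drew the noise independently for each probe and set. The real sets differed in ways shared by many probes, so these rates do not describe the comparison itself.

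Alternatives planned before the data were examined were the values as deposited, median centring, a filter on the dimmest 25% of probes, an offset of 50 in place of the floor, the replicate number as a block, eBayes with trend and robust, array weights, a Welch test per probe, limma treat at 1.2-fold, and leaving out each replicate number or array. The planned fit on the 28 arrays as separate samples became an alternative. Chosen after seeing the data were leaving out each set or the 3 sets that stood apart, an offset of 0.1, and centring each array by blocks of 48 spots and by 6 positions within the spot order.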

Results

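Gene expression was measured on 28 arrays of wild-type Arabidopsis thaliana of the Columbia-0 ecotype. The plants grew on Murashige and Skoog medium, a standard mineral medium for plant culture. The medium held 2% sucrose for 14 arrays and no added sucrose for the other 14. The labels name neither an organ nor an age. Each array gave an intensity for 3439 probes, of which 11.9 to 17.5% were listed at 0. Medians of single arrays differed by up to 1.44 on the log2 scale before normalization, and the number of arrays limits the precision. Arrays with consecutive replicate numbers in a group resembled each other more than other arrays did for 26 of the 28 arrays. They were averaged, which left 7 sets of 2 arrays per group. The exceptions were the arrays of no-sucrose set 3, which correlated at 0.903 with each other and at 0.939 and 0.941 with their closest arrays of other sets.

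The comparison asked which genes differ in expression between plants on medium with sucrose and plants on medium without it. Among the genes higher on sucrose were AT4G02580, which encodes the 24 kDa subunit of respiratory complex I (5.15-fold), and AT5G19940, which encodes a plastid fibrillin (3.57-fold). PSAN, a subunit of photosystem I, and PRK, the phosphoribulokinase of the Calvin cycle, were also higher, by 1.59-fold and 1.95-fold. PSBW, a small subunit of photosystem II, was 2.87-fold lower on sucrose, and chr31, which encodes a chromatin remodeling protein, was 7.39-fold lower. Most sets of the lower group were at or below the signal floor for AT4G02580 and chr31, and with an offset of 0.1 in place of the floor these genes differed by 3.41-fold and 4.42-fold.

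In all, 1033 of the 3439 probes (30.0%) passed an adjusted p of 0.05 in limma, 605 higher and 428 lower on sucrose. Of these, 527 differed by over 2-fold, 256 higher and 271 lower. The arrays of sucrose set 1 lay with the arrays labelled no sucrose, and no-sucrose sets 1 and 2 lay apart from both groups, so directions below are those of the labelled groups. With all 28 arrays as separate samples, the fit planned before the data were examined, 1710 probes passed (961 higher and 749 lower). Without the 3 sets that stood apart 1657 passed (919 higher and 738 lower). Those sets were picked from the same data for lying away from their group. Leaving them out therefore favours larger counts and folds by construction, here and below.

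The balance of higher and lower probes depended on the scaling. After quantile normalization 58.6% of the changed probes were higher on sucrose. The share was 20.4% with the values as deposited (189 higher and 739 lower) and 71.3% with each array centred on its median (1076 higher and 433 lower). These scalings moved the median log2 fold change of all probes to -0.31 and 0.31. Median signals before normalization were 0.163 to 0.213 in sucrose sets 2 to 7 and 0.344 to 0.432 in no-sucrose sets 3 to 7. Centring on the median raised the deposited log2 fold change of every probe by the same amount, also for probes at the floor. Under all 3 scalings 549 probes were called in the same direction, 188 higher and 361 lower. In 67 probes (1.95%) the sets of the groups did not overlap. The average over all possible splits of the sets is 0.0583% where no values are tied. Probes moved together, so the share of a single split can lie far from that average, and this comparison does not measure chance.

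**Figure D1:**
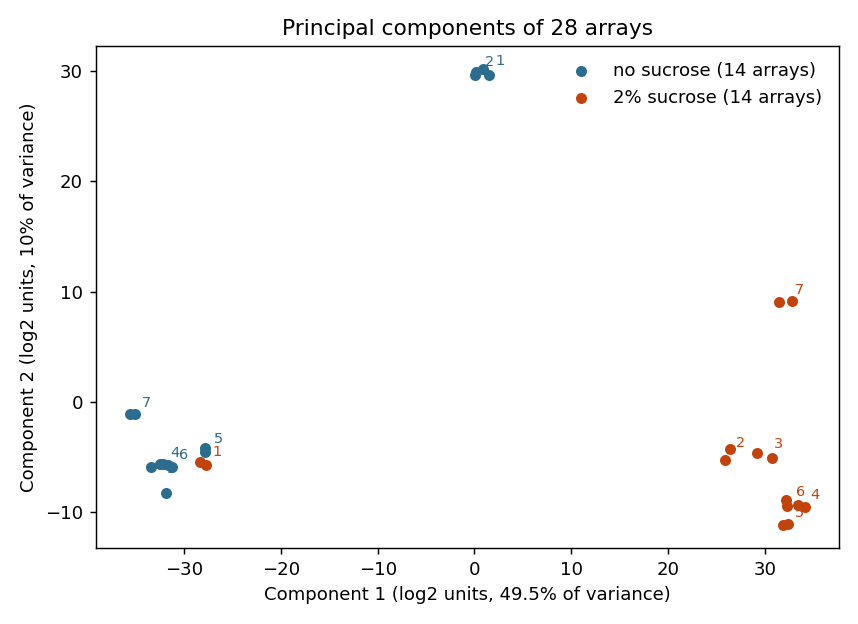
First and second principal components of the 28 arrays, in log2 units, after quantile normalization; each point is an array and each digit the number of its set of 2 arrays. Component 1 holds 49.5% of the variance and component 2 10%; sucrose set 1 lies among no-sucrose sets 3 to 7, and no-sucrose sets 1 and 2 lie apart from both groups.

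Among the 10 increases on sucrose named here were AT3G49740 and AT4G02580, and the order of the 10 changed with the floor, the scaling and the sets kept. AT3G49740, a pentatricopeptide repeat protein gene of a family that acts on organelle RNA, had a mean log2 signal of -1.09 ± 1.26 with sucrose and -3.48 ± 0.66 without (SD, n = 7 sets each). It was 5.24-fold higher, with a log2 fold change of 2.39 ± 0.52 (SE; limma adjusted p = 0.00752), and was at or below the floor in 2 of the 7 no-sucrose sets. AT4G02580 was 5.15-fold higher, with a log2 fold change of 2.37 ± 0.44 (SE; limma adjusted p = 0.00495). Its signal was at or below the floor in 6 of the 7 no-sucrose sets and in 1 sucrose set, so its fold depends on the floor. AT5G15280, of the same repeat family as AT3G49740, was 3.24-fold higher (log2 1.70 ± 0.30, SE; limma adjusted p = 0.00444), and its sets did not overlap between the groups. AT5G19940 rose 3.57-fold and AT3G06870 3.73-fold. AT3G26580 was 3.34-fold higher. AT1G54500, which encodes a rubredoxin-like protein, rose 2.83-fold. TPP2, the tripeptidyl peptidase II gene, rose by a log2 fold change of 1.58, and AT2G04700 and AT1G70350 rose 2.95-fold and 2.79-fold. The 7 genes from AT5G19940 to AT1G70350 had limma adjusted p between 0.00378 and 0.0235. With an offset of 0.1 in place of the floor AT3G49740, AT4G02580 and AT5G19940 were 3.11-fold, 3.41-fold and 2.27-fold higher. With the values as deposited AT3G49740 was 3.38-fold, AT5G19940 2.34-fold, AT2G04700 1.96-fold and AT1G70350 1.79-fold higher. Without the 3 sets that stood apart AT3G06870 was 6.22-fold, AT5G19940 5.39-fold, AT2G04700 4.79-fold and AT1G54500 4.47-fold higher. Centring by spot position on the array ended the call of AT3G49740 at 2.15-fold (limma adjusted p = 0.104).

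Among the 10 changes of each direction named here, the decreases ran from 5.11-fold to 9.04-fold and the increases from 2.79-fold to 5.24-fold. These were the largest among called probes of 1 gene whose higher group had a mean above the median of all probes. For the same genes the decreases ran from 3.97-fold to 7.15-fold and the increases from 2.75-fold to 6.39-fold with each array centred on its median, and from 6.11-fold to 11-fold and 1.79-fold to 4.16-fold as deposited. AT4G13680 was 9.04-fold lower on sucrose, with a log2 fold change of -3.18 ± 0.64 (SE; limma adjusted p = 0.00610). Its log2 signal was -3.11 ± 1.63 with sucrose and 0.07 ± 0.59 without (SD, n = 7 sets each). AT3G50350 was 7.62-fold lower (log2 -2.93 ± 0.55, SE; limma adjusted p = 0.00495), and its sets did not overlap. The log2 fold change of chr31 was -2.89 ± 0.46 (SE; limma adjusted p = 0.00378), and its signal was at or below the floor in 5 of the 7 sucrose sets. AT5G40030 and AT4G17070 were both 7.30-fold lower after rounding. Without sucrose set 1 they were 11.2-fold and 9.36-fold lower, and without the 3 sets that stood apart 19.7-fold and 12.1-fold. AT4G17070 kept a high signal in both groups, at a log2 signal of 1.71 ± 1.09 with sucrose and 4.58 ± 0.72 without (SD, n = 7 sets each). AT1G16080 was 6.71-fold lower and AT4G21770 6.38-fold lower. AT5G63490 and AT4G18180 were 5.94-fold and 5.57-fold lower, and AT4G19900 5.11-fold lower. Signals at or below the floor were seen in 4 of the 7 sucrose sets and in no-sucrose set 1 for AT4G21770, in 3 sucrose sets for AT5G63490, in 2 for AT4G13680 and in 1 for AT3G50350. With an offset of 0.1 in place of the floor AT4G13680 was 4.95-fold lower, chr31 4.42-fold, AT3G50350 5.06-fold, AT4G21770 4.21-fold and AT5G63490 3.32-fold. Without the 3 sets that stood apart AT4G13680 was 16.6-fold lower, AT4G21770 15-fold, AT4G18180 11.5-fold, AT1G16080 10.4-fold, AT4G19900 9.71-fold and AT5G63490 8.97-fold. Without no-sucrose set 1 AT4G21770 was 9.63-fold lower, and with each array centred on its median AT4G17070 was 4.81-fold lower. The limma adjusted p of these 7 genes lay between 0.00389 and 0.0378. AT4G21770, the gene with the highest of these values, lost its call without no-sucrose set 3, 4, 5 or 6 or sucrose set 2, 4, 5, 6 or 7, with adjusted p from 0.0676 to 0.0777. AT4G18180 lost its call without no-sucrose set 3, 4 or 6 or sucrose set 4, with adjusted p of 0.0512, 0.0502, 0.0501 and 0.0523.

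**Figure D2:**
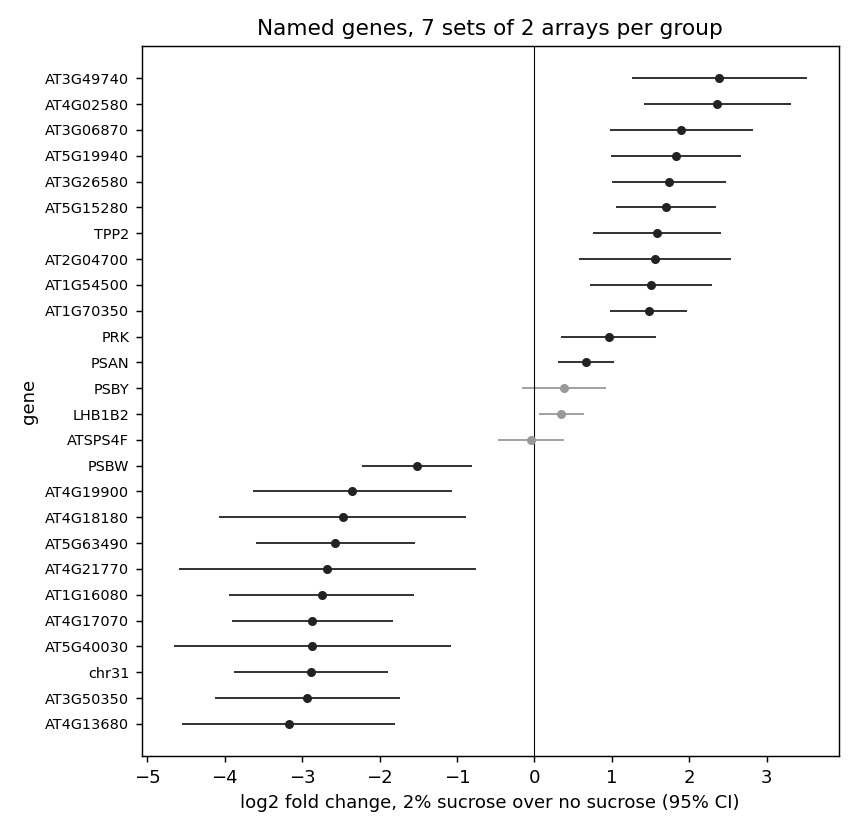
Log2 fold change of the named genes, sucrose over no sucrose, on the x axis, with 1 gene per line; points are limma estimates from 7 sets per group, bars are 95% confidence intervals, and grey marks genes that did not pass an adjusted p of 0.05. The values run from -3.18 for AT4G13680 to 2.39 for AT3G49740.

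The 4 measured light harvesting and photosystem genes did not all move in the same direction: PSBW fell, and the log2 fold changes of PSAN, LHB1B2 and PSBY were positive. Of 40 listed genes, 4 were measured by a probe of 1 gene; 1 rose and 1 fell over all probes, and 2 rose and 1 fell when adjusted over the list alone. PSAN had a log2 fold change of 0.67 ± 0.17 (SE; limma adjusted p = 0.0132), and all 7 sucrose sets lay above the no-sucrose mean. PSBW had a log2 fold change of -1.52 ± 0.33 (SE; limma adjusted p = 0.00737), with 6 of the 7 sucrose sets below the no-sucrose mean; with each array centred on its median it was 1.78-fold lower. The set that lay above it was sucrose set 1, at a log2 signal of 5.60 against 2.97 to 3.92 in the other sucrose sets. LHB1B2, a light-harvesting chlorophyll a/b protein gene, had a log2 fold change of 0.35 ± 0.13 (SE; limma adjusted p = 0.0644). It passed when adjusted over the list alone, and over all probes with 28 arrays as separate samples (adjusted p = 0.0052), with each array centred on its median (adjusted p = 0.0198) or without sucrose set 1 (adjusted p = 0.0454). Over all alternatives its adjusted p ran from 0.0052 to 0.513. PSBY, another photosystem II subunit gene, had a log2 fold change of 0.38 ± 0.25 (SE; limma adjusted p = 0.268), and passed with array weights (adjusted p = 0.0472) and with spot position centred (adjusted p = 0.0224). The directions of these 4 genes were the same under the 3 scalings.

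The list as a whole was not called against the other probes by camera with a preset correlation (p = 0.506) or with an estimated correlation (p = 0.512). fry, which asks whether the genes move one way on balance, gave p = 0.0401 for a rise, and p = 0.104 for change in either direction. The mean log2 fold change of the list was -0.03 and its median 0.37, so these differed in sign, and the median had the sign of the tests.

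Carbon metabolism genes were few on the list of measured genes. Of 26 Calvin cycle and photorespiration genes, PRK and SBPASE were measured, and 1 rose, over all probes and when adjusted over the list alone. PRK had a log2 fold change of 0.96 ± 0.28 (SE; limma adjusted p = 0.0243), with all 7 sucrose sets above the no-sucrose mean. It was not called with the values as deposited (log2 0.57, limma adjusted p = 0.115) nor without no-sucrose set 3 (log2 0.89, limma adjusted p = 0.0506). SBPASE, the sedoheptulose bisphosphatase gene, was at or below the floor in all 14 sets, so no fold is given. It was nevertheless called higher with each array centred on its median (adjusted p = 0.0442) and with spot position centred (adjusted p = 0.0227), so these settings gave calls to a probe without signal, and the calls that LHB1B2 and PSBY gained under them carry that limit. Of 28 starch and sucrose metabolism genes, ATSPS4F, a sucrose phosphate synthase gene, was measured. Its log2 fold change was -0.05 ± 0.20 (SE; limma adjusted p = 0.922), with a 95% confidence interval from -0.47 to 0.38. No gene of the other 13 lists was measured by a probe of 1 gene, and none of the 12 sugar-responsive index genes was. The list of cytosolic ribosomal proteins held only 2 genes, so it does not show whether other ribosomal protein genes were measured.

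**Figure D3:**
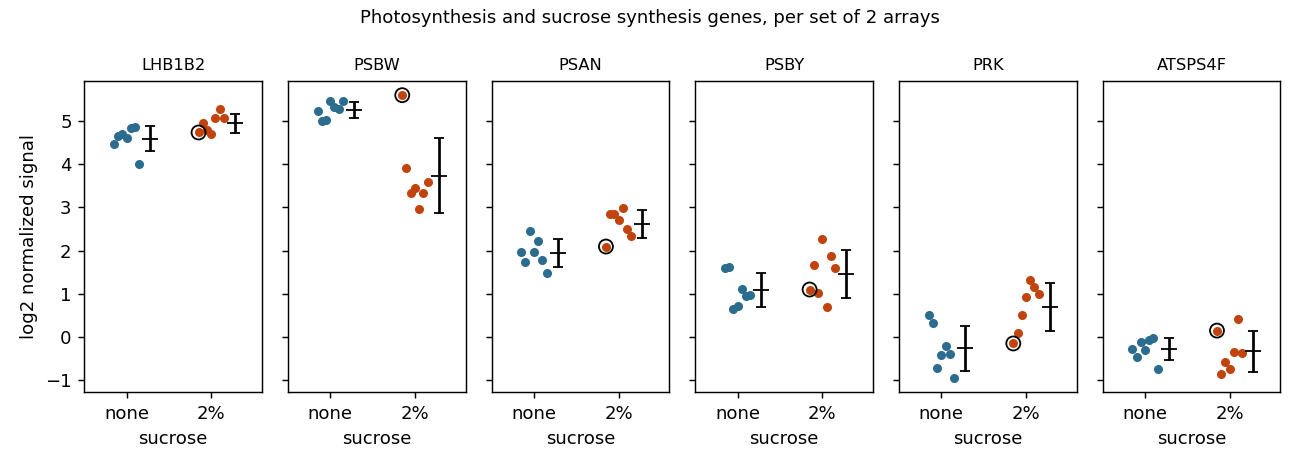
Log2 normalized signal of LHB1B2, PSBW, PSAN, PSBY, PRK and ATSPS4F without and with 2% sucrose; points are sets of 2 arrays (7 per group), bars are the mean and SD, and a black ring marks sucrose set 1. PSBW in sucrose set 1 lies at 5.60, with the no-sucrose sets, and in the other sucrose sets between 2.97 and 3.92.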

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

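Centring by spot position was chosen after seeing the data, with its bound written before the count it gave was known. The tests on sucrose set 1 and on no-sucrose sets 1 and 2 were chosen after the result was seen. The positions and median signals of the sets were added to the values examined for a set far from the others after the sets had been seen to stand apart.

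A set lay far from the others of its group, by Dixon's test, in 14 of 58 groups of values. Chance gives about 1 in 20 for values of normal spread without ties, and some values here were tied at the floor. The groups were also not independent, since most were genes chosen for their difference between the media, so their outliers can come together. Sucrose set 1 was that set in 13 of the 14, which is 1 observation seen in several genes and not separate evidence. Its position was -0.0452, against 1.0 to 1.22 for the other sucrose sets (gap over range 0.829). Its median signal was 0.339, against 0.163 to 0.213 (0.716). Its log2 signals were the lowest of the group for AT5G19940 (0.828), AT1G54500 (0.752) and AT1G70350 (0.702), which were higher on sucrose. They were the highest for AT4G13680 (0.667), chr31 (0.696), AT5G40030 (0.624), AT4G17070 (0.603), AT1G16080 (0.768), AT5G63490 (0.677), AT4G19900 (0.581) and PSBW (0.642), which were lower on sucrose. The remaining one was AT4G02580, where no-sucrose set 2, at a log2 signal of -4.10, was the only set of its group above the floor, so the other values were tied (gap over range 1).

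Sucrose set 1 lay with the no-sucrose sets. An exchange of labels with a no-sucrose set needs a partner near 1 on the axis, and the highest no-sucrose set lay at 0.512. A wrong label, or a sample from outside the sucrose group, remains open: the mean correlation of sucrose set 1 with the no-sucrose sets was 0.938, within the 0.888 to 0.942 of those sets among themselves. A shared array lot or hybridization batch cannot be told apart from this, since 0 batch labels are given; if such a batch separated the arrays, part of the difference between the groups may come from it too. A plant response that failed in this set is also open and was not tested.

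No-sucrose sets 1 and 2 lay between the groups, at 0.512 and 0.464, where the other no-sucrose sets lay between -0.216 and -0.0321. Their median signals before normalization were 0.182 and 0.213, in the range of sucrose sets 2 to 7 (0.163 to 0.213). Those of no-sucrose sets 3 to 7 were 0.344 to 0.432, and that of sucrose set 1 was 0.339. The median signals of all 3 sets that stood apart were thus near those of the other label. Only sucrose set 1 also lay with the other label on the axis. No-sucrose sets 1 and 2 had mean correlations of 0.871 and 0.864 with the sucrose sets. With the other no-sucrose sets these were 0.888 and 0.891. The part of overall signal in the difference between the groups was not tested. A mixture of both kinds of material would leave few probes where both sets lie beyond all other sets on the same side. There were 285 such probes, against at most 226 for another pair of sets of a group. That is more than a mixture was expected to leave. It stays below the bound of over 2 times the highest other pair, which was set for arguing against a mixture, so it does not decide the question. Their residuals off the axis, 0.626 and 0.627, were above the 0.368 to 0.60 of the other sets; that measure was examined first and set aside because a mixture is not a straight line on the log2 scale. A mixture and a different array batch cannot be told apart here, and no biological explanation was tested.

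The number of probes that differed between the groups was 1033. In 2 of 100 of the 1716 splits of the 14 sets into 7 and 7, the real one included, as many probes passed. A random grouping of these sets is thus argued against as the source of the count. The labels name no separate cultures, so the splits cannot speak to a difference between cultures that arose by chance. The highest of the other splits gave 1076 probes, more than the real one. It put sucrose sets 1 and 3 with the no-sucrose sets and no-sucrose sets 1 and 2 with the sucrose sets. Sucrose set 1 and no-sucrose sets 1 and 2 are the sets that stood apart. Each split held 7 sets per side, so with those 3 sets moved a further sucrose set had to move as well. Sucrose set 3 lay with the other sucrose sets, at position 1.1. Whether another sucrose set in its place would give as many probes was not examined. After centring by spot position 1207 probes passed, which argues against position on the array as the whole cause; 823 of the 1033 were called in the same direction and 1 in the opposite one. That spot blocks explained 5.14% of the variance of the fold changes had been seen before this count. Sucrose in the medium, an unrecorded batch and the overall signal of the arrays remain open as sources of the difference.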

How the results depend on the processing

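Averaging to sets, the offset of 0.1, and the fits without the sets that stood apart, without each set and with spot position centred were chosen after seeing the data; the fit on 28 arrays was the planned one. Of the 1033 changed probes (605 higher, 428 lower), all 1033 were also called with 28 arrays as separate samples, which gave 1710 (961 higher, 749 lower). Without the 3 sets that stood apart 992 of them were called, and that fit gave 1657 (919 higher, 738 lower). The 3 sets were picked for standing apart, so that fit favours larger counts by construction. Array weights gave 1842 (1008 higher, 834 lower) and limma treat against 1.2-fold 449 (251 higher, 198 lower), a stricter question by construction. With the values as deposited 189 were higher and 739 lower, and with median centring 1076 were higher. Sucrose sets 2 to 7 had lower medians before normalization than no-sucrose sets 3 to 7, which lowers the deposited log2 fold changes. Median centring raised every log2 fold change by the same amount. SBPASE, at or below the floor in all 14 sets, thereby had a log2 fold change of 0.62 (limma adjusted p = 0.0442). The 1076 may therefore hold other probes without signal. Array weights are estimated from the same data and count sets less that lie far from their group, so that fit also favours larger counts by construction. The weights of single sets were not examined. Leaving out a set, an array or a replicate number gave 764 to 1431 changed, 457 to 810 higher and 307 to 621 lower, with the highest counts without sucrose set 1 and the lowest without no-sucrose set 6. Apart from the replicate block, the other settings stayed within 1.5 times of each count.

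The replicate numbers did not pair the samples in a regular way. Sets of the same number correlated at over 0.1 in their deviations for 1 of 7 numbers, and 1 sucrose set was closest to its own number. For number 1 the correlation was -0.516, against -0.0817 to 0.128 for the others. Set 1 lay toward the opposite group in both media, at positions -0.0452 and 0.512. With the replicate block 416 probes passed over the sets (227 higher, 189 lower) and 1611 over the 28 arrays (893 higher, 718 lower). The labels do not say whether the numbers pair samples, so the lower count over the sets stays a limit.

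For the photosystem list, camera gave p between 0.150 and 0.822 over its alternatives, and fry, which asks another question, 0.0401. No named gene that was called reversed direction. Named genes that lost a call were AT4G21770 under the Welch test, AT4G21770 and AT5G40030 with an offset of 50, PRK as deposited and AT3G49740 with spot position centred. The 5 that lost it under treat were AT2G04700, AT4G21770, AT4G18180, PSAN and PRK. The 10 under the block over sets were AT3G06870, AT5G19940, TPP2, AT2G04700, AT1G54500, AT5G40030, AT4G21770, AT4G18180, AT4G19900 and PRK (limma adjusted p from 0.0505 to 0.124). AT4G21770, AT4G18180 and PRK also lost it without certain single sets. The filter on dim probes removed AT4G02580 and SBPASE, which were then not tested. LHB1B2 passed under the block over 28 arrays (adjusted p = 0.00699). Of the 23 called named genes, the fold moved by over 1.5 times in 12 without the 3 sets that stood apart, 8 with an offset of 0.1, 6 with array weights, 4 as deposited and 2 with median centring. With an offset of 50, which exceeds most intensities, it moved so in all 23, and no fold was above 1.4 there. With no background measured, signals near the floor limit the folds of dim genes.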

Other observations

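The gene groups in this part were put together after their values were seen, so their counts describe these arrays and are not tests of the groups. Calls and folds gained without the 3 sets that stood apart are favoured by the choice of those sets. Genes for mitochondrial electron transfer went both ways. AT5G47890, the B8 subunit of respiratory complex I, was 2.19-fold higher on sucrose (log2 1.13 ± 0.28, SE; limma adjusted p = 0.0115), like the 24 kDa subunit gene AT4G02580. ETFQO, which passes electrons from the electron transfer flavoprotein to ubiquinone, was lower by a log2 fold change of -0.31 ± 0.11 (SE; limma adjusted p = 0.0411). AT5G47890 was not called with the values as deposited (log2 0.54, limma adjusted p = 0.105). ETFQO was not called with median centring (log2 -0.34, limma adjusted p = 0.154), and its log2 fold change was -0.96 as deposited.

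Of 9 genes for the assembly or function of the photosynthetic electron transfer chain, LPA19 and ATAB2 passed, both higher. LPA19, a photosystem II assembly factor gene, was 2.3-fold higher (95% confidence interval of the log2 fold change 0.60 to 1.79; limma adjusted p = 0.00894). It was called under the 3 scalings, but its log2 fold change was 1.2 in the main fit and 0.55 with the values as deposited. ATAB2 was 1.54-fold higher (limma adjusted p = 0.0194) and had a log2 fold change of 0.01 with the values as deposited. PSB27 (log2 -0.43), CCB3 (-0.46), NdhS (-0.07), CRR21 (-0.26) and PIFI (0.07) did not pass, CRR41 was at or below the floor in all 14 sets, and NdhN in most of them. These calls changed with the scaling and the sets kept: as deposited ATAB2 was not called and CCB3 and CRR21 were called lower (limma adjusted p = 0.0410 and 0.0435), and without the 3 sets that stood apart CCB3 was called lower (limma adjusted p = 0.00552). With median centring NdhN and CRR41 were called higher (limma adjusted p = 0.0376 and 0.0442). The call of CRR41 rests on no measured signal. NdhN was at or below the floor in 5 of 7 sucrose and 6 of 7 no-sucrose sets, so its call rests on few sets with signal.

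Of 4 genes for tetrapyrrole and carotenoid synthesis, 2 passed as lower and 1 as higher. Z-ISO, the carotenoid isomerase that acts on zeta-carotene, was 3.37-fold lower on sucrose (log2 -1.75 ± 0.56, SE; limma adjusted p = 0.0329) and was called under the 3 scalings. It was at or below the floor in 3 of the 7 sucrose sets, and its log2 fold change was -2.56 without the 3 sets that stood apart. HEMA3, a glutamyl-tRNA reductase gene, was 1.49-fold lower (limma adjusted p = 0.0191), and SIRB, the sirohydrochlorin ferrochelatase gene of siroheme synthesis, was 1.77-fold higher (limma adjusted p = 0.00495). CHLM, a magnesium protoporphyrin methyltransferase gene, had a log2 fold change of 0.36 (limma adjusted p = 0.0687), and -0.24 with the values as deposited; it was called higher without the 3 sets that stood apart (log2 0.49, limma adjusted p = 0.0127). HEMA3 was not called with median centring (limma adjusted p = 0.128) or without those 3 sets (limma adjusted p = 0.0533), nor SIRB with the values as deposited (limma adjusted p = 0.617).

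Of 4 genes of glycosyl hydrolase family 9, which holds plant endoglucanases, GH9B12 was 2.29-fold higher (limma adjusted p = 0.0352) and GH9B8 1.77-fold lower (limma adjusted p = 0.0220). GH9B16 (log2 -1.14) and GH9B11 (log2 0.08) did not pass, and GH9B11 had a log2 fold change of -0.52 as deposited. Without the 3 sets that stood apart GH9B16 was called lower (log2 -2.16, limma adjusted p = 0.000167) and GH9B12 had a log2 fold change of 1.79. GH9B12 was not called as deposited (limma adjusted p = 0.0920). Signals at or below the floor were seen in 3 sucrose sets and 1 no-sucrose set for GH9B8 and in 2 and 1 for GH9B16. The calmodulin-like genes CML41 and CML30 were 2.26-fold and 1.85-fold lower (limma adjusted p = 0.00718 and 0.0351), and CML30 was not called with median centring (limma adjusted p = 0.110). The log2 fold change of CML41 was -1.17 in the main fit and -1.78 with the values as deposited.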
